A study of Mus musculus with 24 samples.

How the data were processed

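RNA from 24 mouse livers was measured on a whole-transcript Affymetrix mouse array, with 1 array for each liver. The samples formed 8 groups of 3 mice, and the mouse identifiers differ throughout, so that replicates were separate animals. Per the labels' protocols, livers were snap-frozen, total RNA passed an integrity check before use, and the RNA was labelled with biotin in a whole-transcript sense target assay. The deposited values are log2 expression levels for each probe set, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, normalises the quantiles of the probes between arrays and summarises the probes of a probe set. The RMA program, the chip definition and the set of arrays normalised together are not given in the sources used here. The values themselves ran from 0.68 to 13.48 and were not centred by gene. No detection call came with the values, and the number of arrays limits the precision.

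The deposited table held 35556 probe sets. Of these, 21218 were paired with 1 gene symbol in the probe table, 1881 with several symbols and 12457 with no gene. Entrez identifiers of 21185 probe sets with 1 symbol matched the RefSeq gene table of assembly GRCm38.p6, 33 did not, and the update changed 0 symbols. These probe sets stood for 18820 genes, of which 1386 had several probe sets. The probe set with the highest mean over all 24 arrays represented such a gene. All 18820 genes were tested without a filter, on the values as deposited. Probe sets with several symbols or none were fitted apart.

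Groups were compared with limma 3.58.1 in R 4.3.3, by linear models with moderated variances on the log2 values. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison. A gene was called at an adjusted p under 0.05, with no fold threshold. There were 6 comparisons, 4 of them between genotypes within 1 experiment. Each comparison of a pair of groups used its own 6 arrays. The difference between the JNK effects after bile duct ligation and after diethylnitrosamine was an interaction term over 12 arrays. The comparison of livers labelled control after the 2 injuries was secondary. A rank or permutation test of 3 against 3 livers cannot give an exact p below 0.1, so that single-gene p-values came from limma alone. The labels and series description name no statistical test.

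Before the data were examined, 32 gene lists were fixed, with 4 to 29 measured genes each. They covered biliary epithelium, hepatocyte function, bile acid synthesis and transport, PPARalpha targets, fibrosis and stellate cells, macrophages and Kupffer cells, T and NK cells, B and plasma cells, neutrophils and sinusoidal endothelium. They also covered the cell cycle, oncofetal and liver tumour markers, cell death and necroptosis, NF-kB targets, AP-1 and immediate early genes, p53 targets, ER stress, NRF2 and glutathione, xenobiotic receptor targets, fatty acid and triglyceride synthesis, cholesterol synthesis, the interferon response, MHC class II, Notch and YAP targets and the acute phase. The circadian clock, female-biased and male-biased liver genes, sex chromosome genes, exocrine pancreas, adipose tissue and mesothelium, and erythroid cells completed the set. Some genes stood on more than 1 list. Each list was tested with limma's camera at its preset correlation of 0.01, adjusted over the 32 lists of a comparison. Camera with an estimated correlation and fry, a directional test without a comparison to other genes, were run beside it. Members past the threshold were counted over all genes and adjusted over the list alone.

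The genes named were chosen by a rule also set before the data were examined. It took Mapk8, Mapk9 and Ikbkg, then the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, and up to 3 called members of each list by smallest p. Where fewer than 5 genes passed in a direction, those that passed and the 5 with the smallest unadjusted p were taken as values. Names that are only predicted-gene, olfactory, vomeronasal, microRNA or small nucleolar RNA identifiers were left out, except as targets or list members. In lists without a called member at most 2 members were given as values. Genes absent from the array were not analysed here.

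The procedures were tested on simulated data with 18820 genes, of which 200 were changed, at the spread of each comparison. At a change of 1 on the log2 scale, 66 percent of changed genes were called for the 52-week comparison, 54 percent for diethylnitrosamine, 75 percent for bile duct ligation, 47 percent for the 8-week comparison, 45 percent for the interaction and 63 percent for the 2 injuries. At a change of 2 the shares were 97, 91, 98, 87, 87 and 96 percent in the same order. False calls numbered 6, 10, 9, 9, 13 and 4. The simulated genes varied independently of one another. With no list effect, 0 lists were called in each, which does not measure false calls among the correlated genes of real livers. A list given a common shift had a camera adjusted p between 5.74e-13 and 0.0493 over the comparisons, and between 0.0346 and 0.75 with an estimated correlation.

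The alternatives were a filter for genes with a log2 value of at least 5 in at least 3 arrays, quantile normalisation of the arrays fitted, centring each array on its median, a variance trend, all 24 arrays fitted together, array quality weights, the replicate number as a block, the mean of all probe sets of a gene, and leaving out each liver in turn. Centring used the median of the genes tested in each array, not of all its probe sets. Further alternatives were chosen after seeing the data. These were the number range of the mouse identifiers as a block after diethylnitrosamine, the animal series as a block after bile duct ligation, and counts of called list members under each setting. Neighbouring genes were taken from the RefSeq gene table for their order alone, since no genome build is named for the array. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.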

Results

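Gene expression was measured in the livers of 24 mice, in 8 groups of 3. The first experiment compared untreated mice aged 52 weeks. Their hepatocytes lacked NEMO, the regulatory subunit of the IkB kinase complex encoded by Ikbkg, together with the kinases JNK1 and JNK2, encoded by Mapk8 and Mapk9, or the mice were labelled control. In the next experiments JNK1/JNK2 knockout mice and mice labelled control were examined 40 days after diethylnitrosamine, a liver carcinogen, and 28 days after bile duct ligation, a surgical model of cholestasis. The last compared mice labelled as NEMO/JNK1 knockouts with mice labelled as NEMO knockouts at 8 weeks. The ages of the treated mice are not given. The series title asks how JNK1 and JNK2 in hepatocytes set cell fate during liver carcinogenesis. Over all probe sets, the median log2 value of each array lay between 4.52 and 4.66. Arrays of the same group correlated with r between 0.966 and 0.987 across probe sets.

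The targeted genes were read first. Mapk8 had a mean log2 value of 5.65 ± 0.11 (SD, n = 3) in the NEMO/JNK knockouts and 6.52 ± 0.18 in their livers labelled control. After diethylnitrosamine it stood at 5.88 ± 0.11 in JNK knockouts and 6.53 ± 0.14 in livers labelled control, and after bile duct ligation at 5.69 ± 0.3 and 6.71 ± 0.15. At 8 weeks it was 6.05 ± 0.35 in livers labelled NEMO/JNK1 and 6.67 ± 0.16 in livers labelled NEMO. Mapk8 therefore fell by 0.87 (SE 0.13) on the log2 scale at 52 weeks, with a limma adjusted p of 0.00259. It fell by 1.02 (SE 0.16) after bile duct ligation, with an adjusted p of 0.0299. That call was lost without control replicate 1 (adjusted p = 0.106), control replicate 2 (0.055), JNK replicate 1 (0.107) or JNK replicate 3 (0.125), and with the animal series as a block (0.18), a fit that leaves 1 control liver to set against the 3 knockouts. The differences of −0.64 after diethylnitrosamine (adjusted p = 0.985) and −0.61 at 8 weeks (adjusted p = 0.602) did not pass over all genes. Their SEs were 0.13 and 0.2, and their unadjusted limma p-values 0.00168 and 0.0184. Ikbkg fell by 0.85 at 52 weeks, from 7.3 ± 0.26 in livers labelled control to 6.45 ± 0.02 in the knockouts (adjusted p = 0.0043). It was 7.14 ± 0.33 and 6.98 ± 0.34 in control and JNK knockout livers after diethylnitrosamine, and 7.39 ± 0.11 and 7.02 ± 0.04 after bile duct ligation. At 8 weeks Ikbkg was 7.07 ± 0.24 in livers labelled NEMO and 6.92 ± 0.14 in livers labelled NEMO/JNK1. These levels were about as high as the 6.98 and 7.02 of JNK knockouts after diethylnitrosamine or ligation, which keep NEMO by label, and above the 6.45 of the NEMO/JNK knockouts at 52 weeks. Ikbkg thus did not show the loss of NEMO that the labels give for the 8-week livers, and no liver labelled control was measured at that age. The share of cells other than hepatocytes and the part of the transcript that the probe set covers were not tested. These values therefore cannot decide whether the label is right. The 8-week livers are named here by their labels alone, which limits every direction drawn between them.

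Mapk9 went against the label control. Its mean was 8.34 in livers labelled NEMO and 8.39 in livers labelled NEMO/JNK1 at 8 weeks, both of which keep JNK2 by label. It lay between 2.82 and 3.51 in all 18 other livers, with a mean of 3.17 ± 0.2 in the 9 livers labelled control. The group means of these were 3.24 at 52 weeks, 3.16 after diethylnitrosamine and 3.1 after bile duct ligation, against 2.96, 3.07 and 3.15 in the knockouts of the same experiments. On this evidence the comparisons with livers labelled control did not contrast animals with and without Mapk9 transcript. Every direction given against those livers carries this limit.

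**Figure D1:**
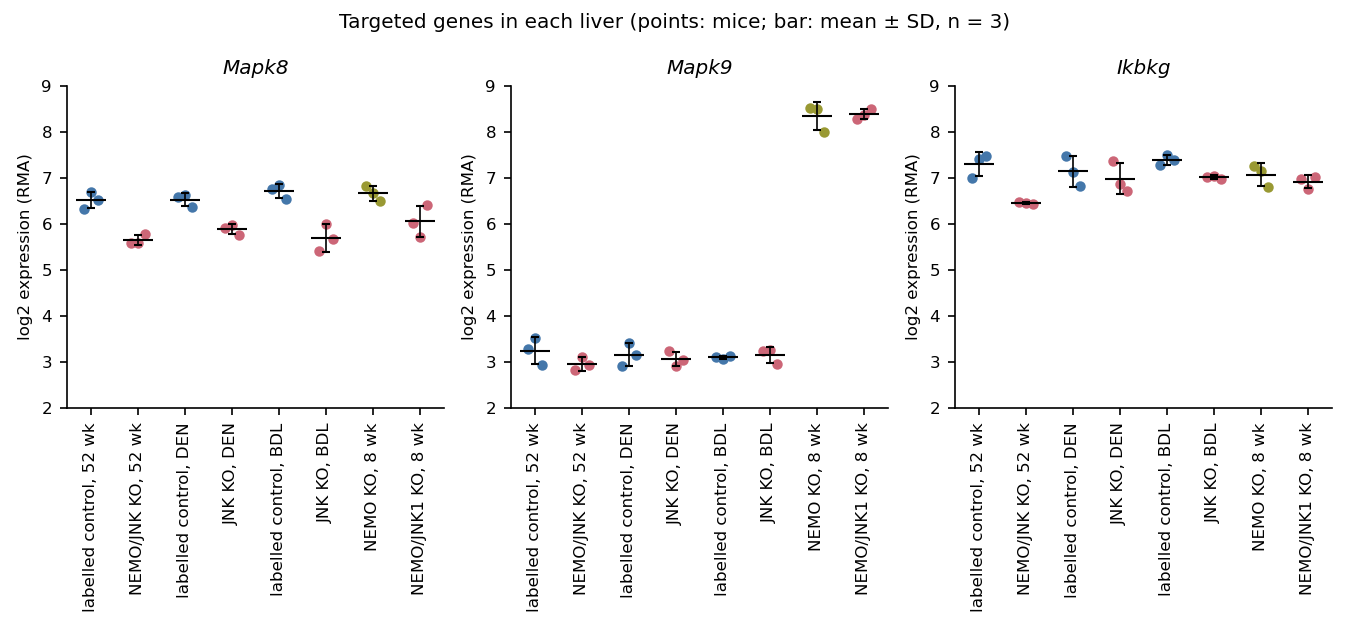
Log2 expression of Mapk8, Mapk9 and Ikbkg in each of the 24 livers, by group, with points for single mice and bars for the group mean and SD (n = 3). Mapk9 lies between 2.82 and 3.51 in 18 livers, livers labelled control included, and between 7.99 and 8.53 in the 6 livers of the 8-week experiment.

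The 52-week comparison concerns at most the combined loss of NEMO and JNK1 in hepatocytes, since Mapk9 signal was absent from both groups. The largest list median was that of genes of the biliary epithelium, the cells that line bile ducts. Of 22 measured members 21 rose and 0 fell, with a median log2 difference of 2.81. Krt19, a keratin of bile duct cells, rose from 5.06 ± 0.46 in livers labelled control to 9.46 ± 0.46 in the knockouts (21.16-fold, SE 0.28 log2, adjusted p = 4.35e-05). Mmp7, a matrix protease made by cholangiocytes, rose from 4.39 ± 0.73 to 9.5 ± 0.12 (34.44-fold, SE 0.31 log2, adjusted p = 3.63e-05). Tspan8 rose by 4.22 (SE 0.23) and Cd24a by 4.15 (SE 0.23). Other epithelial genes were among the largest rises. Dmbt1, a secreted mucosal glycoprotein, went from 6.51 ± 0.43 to 11.27 ± 0.17, and Muc1, a membrane mucin, from 5.0 ± 0.62 to 9.7 ± 0.35. Slc4a9, a bicarbonate transporter, rose by 4.79 and Gabrp by 4.57. Krt20 rose by 4.43 from a mean of 3.17, within the range of Mapk9 in the livers without its signal, so that this rise is at most a lower bound. The camera adjusted p of the biliary list was 7.72e-20, and its adjusted p = 0.233 with an estimated correlation.

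Notch and YAP targets, a group tied to biliary fate and growth control, rose in 14 of 20 members and fell in 0 (median 0.72). The YAP targets Ankrd1, Ccn2 and Ajuba rose by 2.94 (SE 0.14), 2.47 (SE 0.17) and 2.21 (SE 0.15). The list's camera adjusted p was 4.89e-10, and adjusted p = 0.233 with an estimated correlation. Of 15 oncofetal and liver tumour markers 10 rose and 1 fell (median 1.95, camera adjusted p = 3.29e-06, adjusted p = 0.192 with an estimated correlation). Afp, the fetal serum protein used as a marker of liver cancer, rose from 3.73 ± 0.18 to 5.14 ± 0.16. Its adjusted p was 0.000322, and 0.2 when all 24 arrays were fitted together. Tff3, a secreted trefoil factor, rose by 3.5 (SE 0.2), and Golm1, a Golgi protein released in liver disease, by 2.47 (SE 0.21). The 1 oncofetal member that fell did not pass without control replicate 1, control replicate 2 or knockout replicate 2, where 0 fell, and 3 fell with each array centred on its median.

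The cell cycle list rose in 20 of 27 members and fell in 0 (median 0.77). Ccnb2, a mitotic cyclin, rose by 1.94 (SE 0.21). Rrm2, a subunit of ribonucleotide reductase, went from 5.37 ± 0.14 to 6.53 ± 0.06, and the mitotic kinase Cdk1 rose by 0.77 (SE 0.12), a call lost when all 24 arrays were fitted together (0.06). The camera adjusted p was 4.48e-10, and adjusted p = 0.443 with an estimated correlation. Without knockout replicate 1 or without knockout replicate 3 the members risen numbered 12. Cell death and necroptosis genes rose in 7 of 24 (median 0.24, camera adjusted p = 0.0137, adjusted p = 0.554 with an estimated correlation). They included the death receptor Tnfrsf10b (1.47, SE 0.19) and the apoptosis regulators Bcl2l11 (1.18) and Bcl2l1 (1.01). AP-1 and immediate early genes rose in 5 of 18 (median 0.32, camera adjusted p = 0.0148, adjusted p = 0.443 with an estimated correlation), with Gadd45b at 1.65 and Myc at 1.37. Among p53 targets 6 of 21 rose and 1 fell (median 0.35, camera adjusted p = 0.0199, adjusted p = 0.554 with an estimated correlation). Plk2 rose by 0.98 and Perp fell by 0.85. With dim genes filtered out the camera adjusted p of these lists was 0.136 for cell death, 0.233 for AP-1 and 0.117 for p53. Without control replicate 1 it was 0.0598 for cell death and 0.101 for AP-1, and without control replicate 3 it was 0.0541 for p53. Without control replicate 1 the p53 targets that fell numbered 3. With each array centred on its median 6 cell death genes rose and 6 fell, 3 p53 targets rose and 4 fell, and 5 AP-1 genes rose and 2 fell. With quantile normalisation the numbers were 6 and 2, 4 and 3, and 5 and 1.

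The lists of immune cell markers differed in how many of their members rose. Macrophage and Kupffer cell genes rose in 16 of 20 members and fell in 1 (median 1.2, camera adjusted p = 3.74e-08, adjusted p = 0.443 with an estimated correlation). Gpnmb, a marker of lipid-laden and scar-associated macrophages, rose from 4.99 ± 0.84 to 8.19 ± 0.46, Cd68 by 1.76 (SE 0.23) and the complement gene C1qb by 1.44 (SE 0.19). The fall of 1 member was lost without control replicate 2, control replicate 3, knockout replicate 1 or knockout replicate 3. T and NK cell genes rose in 9 of 19 (median 0.8, camera adjusted p = 0.000127, adjusted p = 0.443 with an estimated correlation), with Thy1 up by 2.32 (SE 0.34), Nkg7 by 1.47 (SE 0.14) and Cd8a by 1.14 (SE 0.15). The 9 became 5 without control replicate 2, control replicate 3 or knockout replicate 1, and 4 without knockout replicate 3. With quantile normalisation 6 rose, and with arrays centred 7 rose and 2 fell. MHC class II genes rose in 6 of 7 (median 1.51, camera adjusted p = 6.24e-05, adjusted p = 0.443 with an estimated correlation). H2-Eb1 rose by 1.86 and H2-Aa by 1.66, calls that were lost when all 24 arrays were fitted together.

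B and plasma cell genes rose in 4 of 14 (median 0.43), led by the immunoglobulin genes Ighm (3.5, SE 0.47) and Jchain (3.32, SE 0.57). Their camera adjusted p was 0.0461, and adjusted p = 0.702 with an estimated correlation. It was 0.0882 without control replicate 2, 0.294 without control replicate 3, 0.128 without knockout replicate 1, 0.108 without knockout replicate 3 and 0.0731 with dim genes filtered out. With quantile normalisation 2 B and plasma cell genes rose, and with arrays centred 4 rose and 1 fell. Interferon response genes rose in 10 of 25 (median 0.72, camera adjusted p = 1.57e-05, adjusted p = 0.554 with an estimated correlation). Gbp2 rose by 1.56 (SE 0.21), Oas2 by 1.53 (SE 0.19) and Irf7 by 1.51 (SE 0.23). The count was 5 without control replicate 1, control replicate 3 or knockout replicate 1, and 16 without control replicate 2. Among neutrophil genes 1 of 13 rose, the receptor gene Csf3r (1.04, SE 0.3, adjusted p = 0.0397), with a list median of 0.47 and a camera adjusted p of 0.105. Csf3r was not called without control replicate 1 (0.124), control replicate 3 (0.121), knockout replicate 2 (0.107) or knockout replicate 3 (0.103), nor with quantile normalisation (0.106), centring (0.0583), all 24 arrays (0.0648) or weights (0.0538). Without control replicate 2 the neutrophil genes risen numbered 3.

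Fibrosis and stellate cell genes rose in 9 of 27 members and fell in 1 (median 0.61, camera adjusted p = 0.000181, adjusted p = 0.554 with an estimated correlation). Loxl1, a collagen and elastin cross-linking enzyme, rose from 4.51 ± 0.31 to 5.75 ± 0.12, and the matrix proteoglycan Bgn by 1.07 (SE 0.16). Lrat, which stores retinol in quiescent stellate cells, went the other way, from 8.09 ± 0.63 to 5.91 ± 0.32. Without control replicate 2 the members risen numbered 14, and those fallen numbered 2 without knockout replicate 2 or with arrays centred. NF-kB targets rose in 5 of 21 and fell in 1 (median 0.11, camera adjusted p = 0.134). The adhesion molecules Vcam1 and Icam1 rose by 2.26 (SE 0.24) and 1.22 (SE 0.14), and Sod2, a mitochondrial superoxide dismutase, fell by 0.78 (SE 0.11). Without knockout replicate 1 the NF-kB targets risen numbered 3. With arrays centred 3 rose and 5 fell, and with quantile normalisation 4 rose and 3 fell.

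Hepatocyte programmes of lipid metabolism were lower in the knockouts. Fatty acid and triglyceride synthesis genes fell in 10 of 19 members and rose in 0 (median −0.86, camera adjusted p = 6.49e-05, adjusted p = 0.534 with an estimated correlation). Acacb, an acetyl-CoA carboxylase, fell by 2.26 (SE 0.29), the malic enzyme gene Me1 by 1.46 (SE 0.21) and the regulator Mlxipl by 0.94 (SE 0.14). Cholesterol synthesis genes fell in 12 of 17 and rose in 0 (median −0.66, camera adjusted p = 5.78e-06, adjusted p = 0.534 with an estimated correlation). Idi1 went from 9.54 ± 0.2 to 8.5 ± 0.11, and Dhcr7 fell by 1.05 (SE 0.15). Both calls were lost when all 24 arrays were fitted together. PPARalpha targets, the genes of fatty acid oxidation, fell in 10 of 25 and rose in 1 (median −0.66, camera adjusted p = 0.000133, adjusted p = 0.443 with an estimated correlation). Fabp1, a fatty acid binding protein, fell by 1.07 (SE 0.13), Pex11a by 1.18 and Cpt2 by 0.92. With arrays centred 17 PPARalpha targets fell. Male-biased liver genes had the lowest list median. Of 18 members 16 fell and 0 rose (median −2.43, camera adjusted p = 1.45e-11, adjusted p = 0.269 with an estimated correlation). Mup21, a major urinary protein, went from 8.12 ± 0.27 to 3.58 ± 0.36 (adjusted p = 1.88e-05) and Mup3 from 11.87 ± 0.29 to 7.57 ± 0.75. The bile acid and steroid carrier Slco1a1 went from 8.96 ± 1.37 to 4.25 ± 0.63, and Nudt7 fell by 3.23 (SE 0.22). Beyond the lists, Mup6 went from 10.4 ± 0.13 to 5.66 ± 0.63, Ces1f fell by 4.01 (SE 0.18) and the thyroid hormone deiodinase gene Dio1 by 3.86 (SE 0.29).

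The count for general hepatocyte function depended on the scaling. Of 21 members 3 fell and 0 rose on the deposited scale (median −0.08, camera adjusted p = 0.0963), among them the urea cycle gene Otc, from 11.82 ± 0.15 to 10.94 ± 0.13, and Cyp2f2, which fell by 1.99 (SE 0.32). Without control replicate 1 those fallen numbered 5. With each array centred on its median 15 fell (median −0.41), and with quantile normalisation 3. Bile acid synthesis and transport genes went both ways, with 5 of 29 risen and 9 fallen (median −0.09, camera adjusted p = 0.288). Slc51b, which exports bile acids at the basolateral membrane, rose by 3.46 (SE 0.31) and the sterol exporter gene Abcg5 by 1.85 (SE 0.2), while Baat, which conjugates bile acids, fell by 1.41 (SE 0.14). Without control replicate 1 those risen numbered 3, and with arrays centred those fallen numbered 14. NRF2 and glutathione genes rose in 7 of 18 and fell in 2 (median 0.27, camera adjusted p = 0.0461, adjusted p = 0.592 with an estimated correlation), with Gsta4 up by 0.92 and Cbr3 by 1.16, the latter not called with all 24 arrays (0.4). That list's p was 0.0633 without control replicate 1, 0.0691 without control replicate 3 (where 4 rose), 0.177 without knockout replicate 2 and 0.426 with dim genes filtered out. Without knockout replicate 3, 1 NRF2 member fell, and with arrays centred 4 fell.

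By limma, 2562 of 18820 genes were higher and 1486 lower in the NEMO/JNK knockouts at 52 weeks, 1051 and 252 of them by at least 2-fold. The groups did not overlap for 41.25 percent of genes, where chance gives 10 percent. Camera called 18 of 32 lists, 14 up and 4 down, none of which held with an estimated correlation. The balance of higher and lower genes depended on scaling. Centring each array on the median of its 18820 genes moved the median difference of all genes from −0.045 to −0.371. It gave 1570 higher and 8942 lower genes, while quantile normalisation gave 2122 and 2417. The list medians of cell death (−0.08), NRF2 (−0.06), NF-kB (−0.22), xenobiotic (−0.27) and acute phase genes (−0.07) turned negative with centring, and that of NF-kB (−0.03) also with quantile normalisation. Without knockout replicate 3 the count of genes was 2693. Adjusted over the list alone, 21 biliary, 17 Notch and YAP, 11 oncofetal, 23 cell cycle, 17 macrophage, 10 T and NK, 11 interferon and 15 fibrosis genes were higher. By the same count 11 fatty acid, 13 cholesterol, 13 PPARalpha and 16 male-biased genes were lower.

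**Figure D2:**
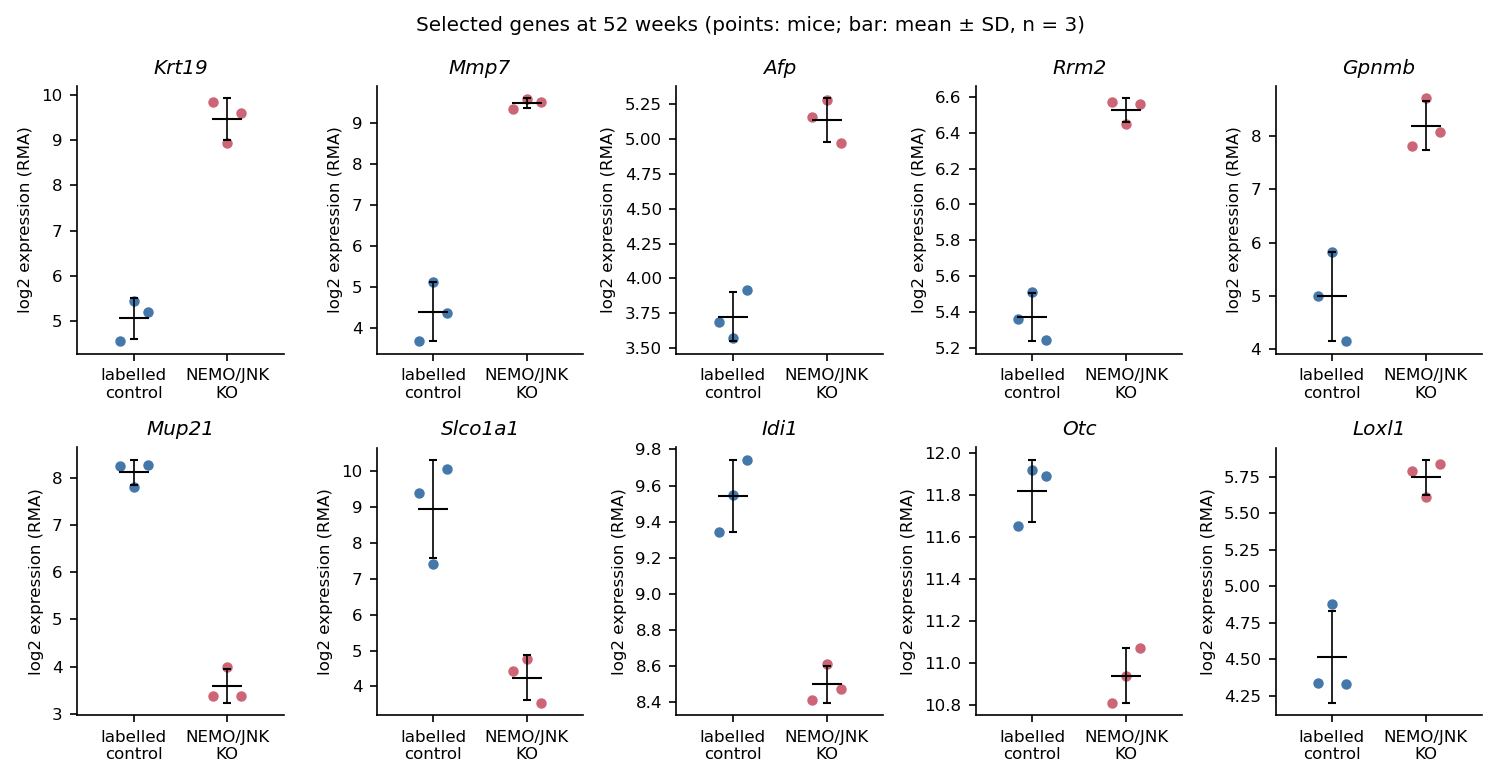
Log2 expression of Krt19, Mmp7, Afp, Rrm2, Gpnmb, Mup21, Slco1a1, Idi1, Otc and Loxl1 in livers at 52 weeks, with points for the 3 mice of a group and bars for mean and SD. Krt19 stands at 9.46 in NEMO/JNK knockouts and 5.06 in livers labelled control, and Mup21 at 3.58 and 8.12.

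The comparison after diethylnitrosamine concerns at most loss of JNK1 in a chemically induced carcinogenesis model, since Mapk9 signal was absent from both groups. Here 0 of 18820 genes passed by limma. The gene list with the smallest camera p was the interferon response, whose 25 members were all higher on average in JNK knockout than in control-labelled livers (median 0.7, camera adjusted p = 4.47e-21, adjusted p = 0.335 with an estimated correlation). Adjusted over the list alone, 11 of the 25 were higher. Oas3, an antiviral oligoadenylate synthetase outside the list, stood at 5.23 ± 0.27 in knockouts and 3.99 ± 0.25 in livers labelled control (SE 0.19, adjusted p = 0.883). Oas2 differed by 1.13 (SE 0.24) and Ifit1 by 1.17 (SE 0.29). The smallest p of all belonged to Phf11a, with 5.12 ± 0.19 against 3.85 ± 0.12 (limma adjusted p = 0.883). Trim30a and Ifi44l, further interferon-inducible genes, differed by 0.82 (SE 0.13) and 0.86 (SE 0.16), and Slc34a2 by 1.14 from a mean of 3.43, within the range of Mapk9 without signal. On the lower side, the smallest p-values were those of Syt12 (−0.83), Ceacam2 (−0.85), Fam83a (−0.81), Mest (−0.62) and Zfp202 (−0.75), each with an adjusted p of 0.985.

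Lists of immune cells were also higher after diethylnitrosamine in the JNK knockouts by camera with its preset correlation, although 0 members passed over all genes and each list named here but NRF2 had adjusted p = 0.555 with an estimated correlation. B and plasma cell genes had a median of 0.64 (camera adjusted p = 6.67e-06), with Jchain at 1.58 (SE 0.79) and Ighm at 1.27 (SE 0.81). MHC class II genes had a median of 0.98 (0.00245), T and NK cell genes 0.34 (0.000554), macrophage genes 0.43 (0.000778), neutrophil genes 0.39 (0.00273) and NF-kB targets 0.28 (0.00123). The biliary list (0.46, 0.000105), fibrosis (0.29, 0.000778), the cell cycle (0.3, 6.67e-06) and cholesterol synthesis (0.27, 0.000554) were called upward as well. Called downward were oncofetal markers (−0.88, 0.000226), sinusoidal endothelium (−0.2, 0.00304), NRF2 genes (−0.24, 0.0128) and the exocrine pancreas (−0.15, 0.00237). Among these NRF2 had adjusted p = 0.588 with an estimated correlation. Among oncofetal markers, Akr1c18 differed by −3.49 (SE 1.64) and Gpc3 by −2.31 (SE 1.81), and 1 was lower adjusted over the list alone. Muc1 of the biliary list differed by 2.25 (SE 0.5).

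Only the interferon, B cell and oncofetal calls survived leaving out each liver in turn. Without JNK replicate 2 the camera adjusted p was 0.912 for the cell cycle, 0.504 for fibrosis, 0.507 for MHC class II, 0.409 for NF-kB, 0.105 for endothelium and 0.0963 for the biliary list. Without JNK replicate 3 it was 0.344 for macrophages, 0.403 for neutrophils and 0.227 for NRF2. Without control replicate 1 it was 0.0572 for macrophages, T and NK cells and neutrophils and 0.954 for cholesterol synthesis. The direction turned downward for the cell cycle without JNK replicate 2 and for cholesterol synthesis without control replicate 1. Without control replicate 2 the adjusted p was 0.0763 for neutrophils, 0.682 for NRF2 and 0.0543 for the pancreas, and without control replicate 3 it was 0.146 for endothelium. The NRF2 list had 0.0559 with the number range of the mouse identifiers as a block, and with dim genes filtered out fibrosis had 0.0768 and NF-kB 0.102.

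The hepatocyte lists were not called after diethylnitrosamine. The median was −0.09 for hepatocyte function (camera adjusted p = 0.243), −0.02 for bile acid genes (0.687), 0.07 for PPARalpha targets (0.196), −0.05 for fatty acid synthesis (0.348) and 0.1 for male-biased genes (0.14). The stress lists gave 0.05 for cell death (0.14), −0.17 for AP-1 (0.206), −0.15 for p53 targets (0.104) and 0.11 for ER stress (0.0692). Of all genes, 781 had an unadjusted p under 0.05, where 941 would by chance, and the groups did not overlap for 9.469 percent of genes against 10 percent by chance. Fry called 0 lists. Without JNK replicate 1 limma called 2 genes. The 3 JNK knockouts were not alike in sex chromosome transcripts: replicate 3 had Xist at 10.38 and the Y-linked Uty at 2.81, while Uty was above 5 in the 23 other livers of the series. Afp followed the number range of the mouse identifiers, at 6.23, 7.54 and 7.62 in control replicates 2 and 3 and JNK replicate 2, and 4.09, 3.83 and 3.77 in the remaining livers. With that range as a block, chosen after seeing the data, 0 genes passed, and 1616 had an unadjusted p under 0.05.

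As a contrast of JNK genes, the comparison after bile duct ligation concerns at most loss of JNK1 during cholestasis, since both groups lacked Mapk9 signal. Control replicates 1 and 2 also came from another animal series than the JNK knockouts. Differences of series or genetic background can therefore enter every direction given here. The changes here were large for single genes but scattered over the lists. Efna3, an ephrin ligand, rose from 4.74 ± 0.06 in livers labelled control to 8.38 ± 0.28 in JNK knockouts (12.45-fold, SE 0.15 log2, adjusted p = 0.000172). Mmrn1, an endothelial and platelet protein, rose from 2.51 ± 0.12 to 5.85 ± 0.75, and A2m, a plasma protease inhibitor, from 4.63 ± 0.44 to 7.66 ± 0.69. Saa3, an acute phase protein, rose from 6.6 ± 0.53 to 9.3 ± 0.14, and Hamp2, a hepcidin, from 5.91 ± 0.49 to 8.6 ± 0.23. Mmd2 rose by 2.65 (SE 0.18) and Prom1, a progenitor and cholangiocyte surface protein, by 2.57 (SE 0.13, and by 1.38 with the mean of its probe sets). By that mean the rise of Efna3 was 2.14.

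Other genes fell after bile duct ligation. BC018473, a gene of unknown function, went from 8.93 ± 0.7 to 3.77 ± 0.08 (−5.16, SE 0.3, adjusted p = 0.000499). In other experiments it varied between livers of the same label, with an SD of up to 2.82 in the NEMO/JNK knockouts at 52 weeks. The group means of BC018473 there lay between 3.48 and 6.34, below that of the ligated livers labelled control. Cyp2c39, a cytochrome P450, went from 11.08 ± 0.22 to 6.83 ± 0.39 (−4.25, SE 0.21, adjusted p = 0.000233), and Dab1, an adaptor of reelin signalling, from 8.15 ± 0.83 to 4.11 ± 0.15. Abhd1 went from 8.85 ± 0.34 to 5.74 ± 0.06, Ifi202b, an interferon-inducible DNA sensor, from 4.91 ± 0.18 to 2.23 ± 0.03, and Tmc5 fell by 2.24. For Abhd1 the group means of the other experiments lay between 5.89 and 6.35, and for Catspere2 between 2.86 and 3.13. In both genes the livers labelled control after ligation stood apart. Catspere2 fell by 2.11 to a mean of 2.91. This mean and the lower means of Mmrn1 and Ifi202b lay under 3.51, the highest Mapk9 value of the livers without its signal, so that these differences are at most lower bounds. BC018473 (adjusted p = 0.0709) and Ifi202b (0.0701) were not called when all 24 arrays were fitted together. Each gene of this and the preceding paragraph kept its call when any 1 liver was left out.

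**Figure D3:**
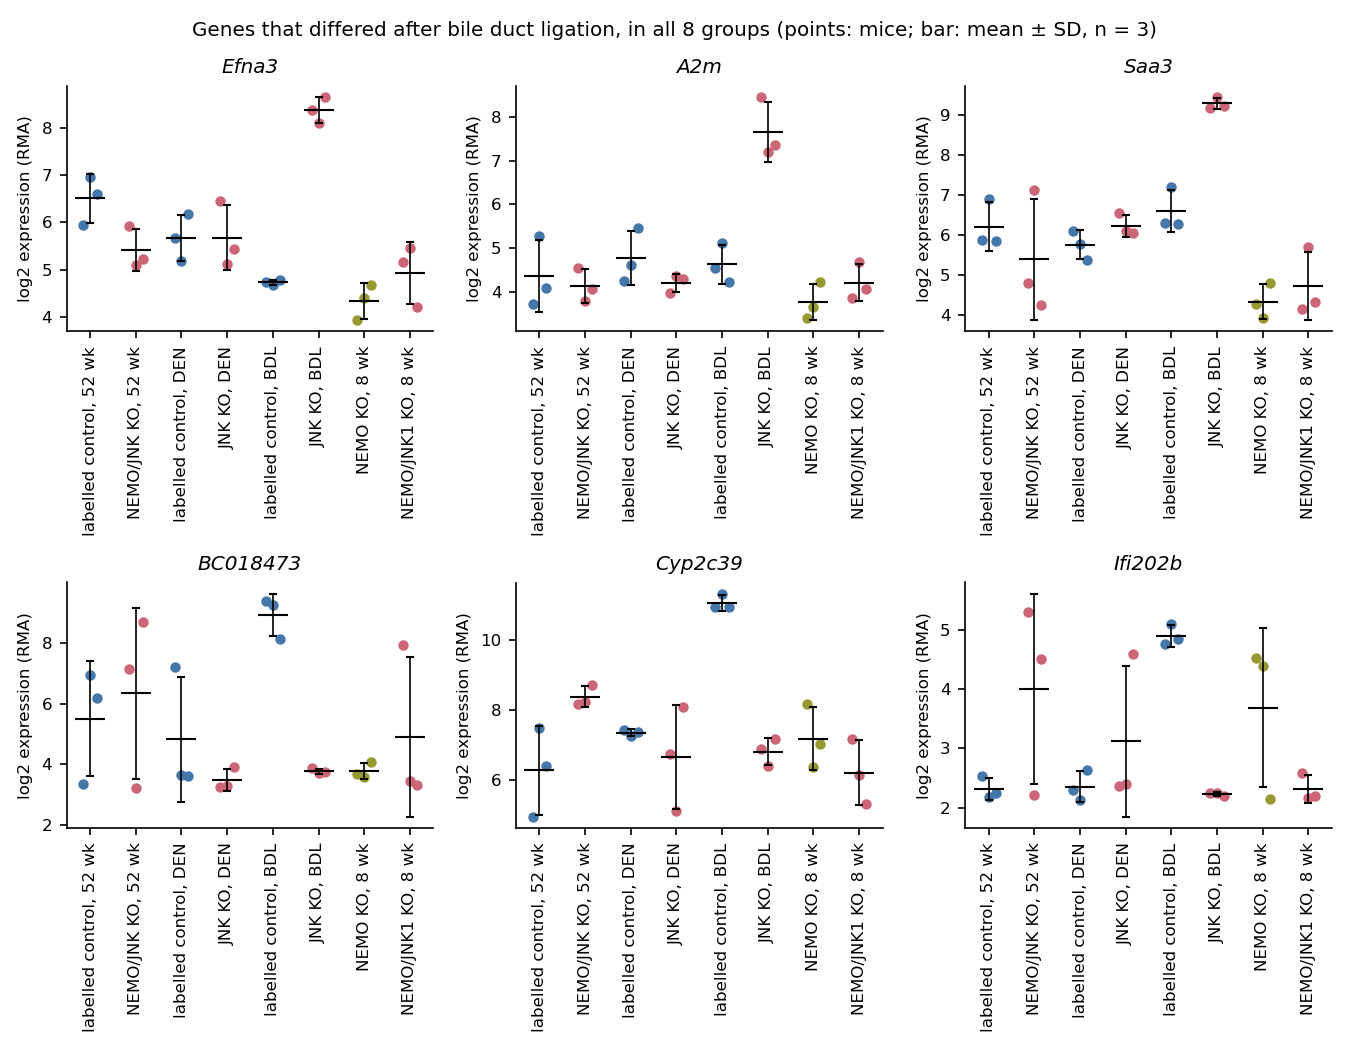
Log2 expression of Efna3, A2m, Saa3, BC018473, Cyp2c39 and Ifi202b in all 8 groups, with points for the 3 mice of a group and bars for mean and SD. Efna3 stands at 8.38 in JNK knockouts and 4.74 in livers labelled control after bile duct ligation, and at 5.67 in both groups after diethylnitrosamine.

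Cell cycle genes had the smallest camera p of the lists after bile duct ligation, with a median of 0.59 (camera adjusted p = 2.02e-09, adjusted p = 0.445 with an estimated correlation). Over all genes 2 of 27 rose, Rrm2 by 1.32 (SE 0.16, adjusted p = 0.0105) and the replication factor Mcm6 by 0.72 (adjusted p = 0.0493), and 7 were higher adjusted over the list alone. The count over all genes was 10 without control replicate 2, 1 without control replicate 1, and 0 when any of the JNK livers was left out. Rrm2 then had adjusted p-values of 0.0542, 0.0701 and 0.0507 and Mcm6 of 0.162, 0.198 and 0.129, without JNK replicates 1, 2 and 3. Mcm6 was also lost without control replicate 1 (0.144) or 2 (0.0814), with quantile normalisation (0.0548) and with arrays centred (0.0683), so that both scalings gave 1 cell cycle gene. Neutrophil genes had a median of 0.59 (camera adjusted p = 4.89e-05, adjusted p = 0.473 with an estimated correlation), with 0 of 13 called over all genes and 7 higher adjusted over the list alone. The list members S100a9 and Ltf had differences of 1.18 (SE 0.3) and 1.07 (SE 0.27). Macrophage genes rose in 2 of 20 (median 0.26, camera adjusted p = 0.000382, adjusted p = 0.473 with an estimated correlation), with 7 higher adjusted over the list alone. Ms4a7 rose by 1.35 (SE 0.14, adjusted p = 0.00621, and 0.17 with all 24 arrays), and the other was Lyz2 (0.61, adjusted p = 0.0382). The macrophage count was 1 when control replicate 1 or any of the JNK livers was left out. Lyz2 was lost without control replicate 1 (0.0847) or 2 (0.056) and without JNK replicates 1 (0.162), 2 (0.176) and 3 (0.117), and with quantile normalisation (0.0542).

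In the other direction, p53 targets had a median of −0.32 (camera adjusted p = 8.51e-05, adjusted p = 0.259 with an estimated correlation), with 2 of 21 fallen and 3 lower adjusted over the list alone. NRF2 and glutathione genes had a median of −0.26 (camera adjusted p = 0.00021, adjusted p = 0.445 with an estimated correlation), with 2 of 18 fallen. Ephx1, an epoxide hydrolase on both lists, fell by 0.85 (adjusted p = 0.0108), and the glutathione transferase gene Gstm3 by 1.42 (adjusted p = 0.0151). The call of Ephx1 was lost without JNK replicate 1 (0.0709) or 2 (0.0725), and that of Gstm3 without control replicate 1 (0.0508), JNK replicate 1 (0.0709) or JNK replicate 2 (0.0898). Without either of those JNK livers 0 members of both lists fell. The p53 and NRF2 counts were each 1 without control replicate 1, and the p53 count was 1 without JNK replicate 3.

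Biliary genes rose in 2 of 22 and fell in 1 after bile duct ligation (median 0.51, camera adjusted p = 0.00714, adjusted p = 0.772 with an estimated correlation), and 7 were higher adjusted over the list alone. Prom1 and Muc1 (2.55, SE 0.31, adjusted p = 0.0104) rose, and the epithelial transcription factor gene Elf3 fell by 1.23 (adjusted p = 0.0308). Muc1 was not called without JNK replicate 1 (0.0554) or 2 (0.0701), 0 members fell without JNK replicates 1, 2 or 3, where Elf3 had 0.131, 0.125 and 0.132, and 2 fell without control replicate 2. The list's camera adjusted p was 0.168 without control replicate 3 and 0.0516 without JNK replicate 1. Acute phase genes rose in 2 of 25, Saa3 and Crp (median 0.16, camera adjusted p = 0.000446, adjusted p = 0.772 with an estimated correlation). That p was 0.203 without control replicate 3, 6 members rose without control replicate 2, and 1 rose without control replicate 1 or JNK replicates 1, 2 or 3, where Crp had 0.1, 0.0554, 0.135 and 0.118. Hepatocyte function genes had 0 of 21 called (median 0.08, camera adjusted p = 0.0211, adjusted p = 0.445 with an estimated correlation), and the p was 0.0629 without control replicate 3 and 0.0578 without JNK replicate 2. B and plasma cell genes had 0 of 14 called (median 0.17, camera adjusted p = 0.0193, adjusted p = 0.445 with an estimated correlation). Their p was 0.0813 without JNK replicate 2 and 0.195 with the animal series as a block. ER stress genes had a median of 0.17 (camera adjusted p = 0.0141, adjusted p = 0.445 with an estimated correlation), and a p of 0.0629 without control replicate 3.

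Fibrosis genes were not shifted as a list after bile duct ligation (median 0.09, camera adjusted p = 0.547). The stellate cell gene Acta2 rose by 1.35 (adjusted p = 0.0276) and Lrat fell by 1.49 (adjusted p = 0.0105). Lrat was not called without JNK replicate 1 (0.0555) or 3 (0.0565), and Acta2 not without JNK replicates 1 (0.134), 2 (0.116) or 3 (0.118), where 0 members of the list rose. Bile acid genes (0.15, 0.29), T and NK cell genes (0.08, 0.209), interferon genes (0.09, 0.233), cell death genes (−0.04, 0.577), NF-kB targets (0.06, 0.388) and Notch and YAP targets (0.13, 0.149) were not called either, each value pair being the median and camera adjusted p. The median of PPARalpha targets was −0.04 and their mean 0.12, with a test directed downward (camera adjusted p = 0.973).

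By limma, 150 genes were higher and 105 lower in JNK knockouts after bile duct ligation, and the groups did not overlap for 20.65 percent of genes against 10 percent by chance. Camera called 10 lists, 8 up and 2 down, none with an estimated correlation, and 16 with the animal series as a block. Mouse identifiers placed control replicates 1 and 2 in another animal series than the remaining 4 livers. The count of 255 genes became 118 with that series as a block, of which 75 were shared. In that fit the JNK effect rests on control replicate 3 alone against 3 knockouts, so that a call kept or lost under it depends on 1 liver. Its leave-one-out counts were 121 and 391 without control replicates 1 and 2, 559 without control replicate 3, and 58, 59 and 97 without JNK replicates 1, 2 and 3. Fitting all 24 arrays gave 116 genes, without Muc1 (0.057), Acta2 (0.0811), Elf3 (0.131), Crp (0.13), Lyz2 (0.613) and Mcm6 (0.383), and array weights gave 391.

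**Figure D4:**
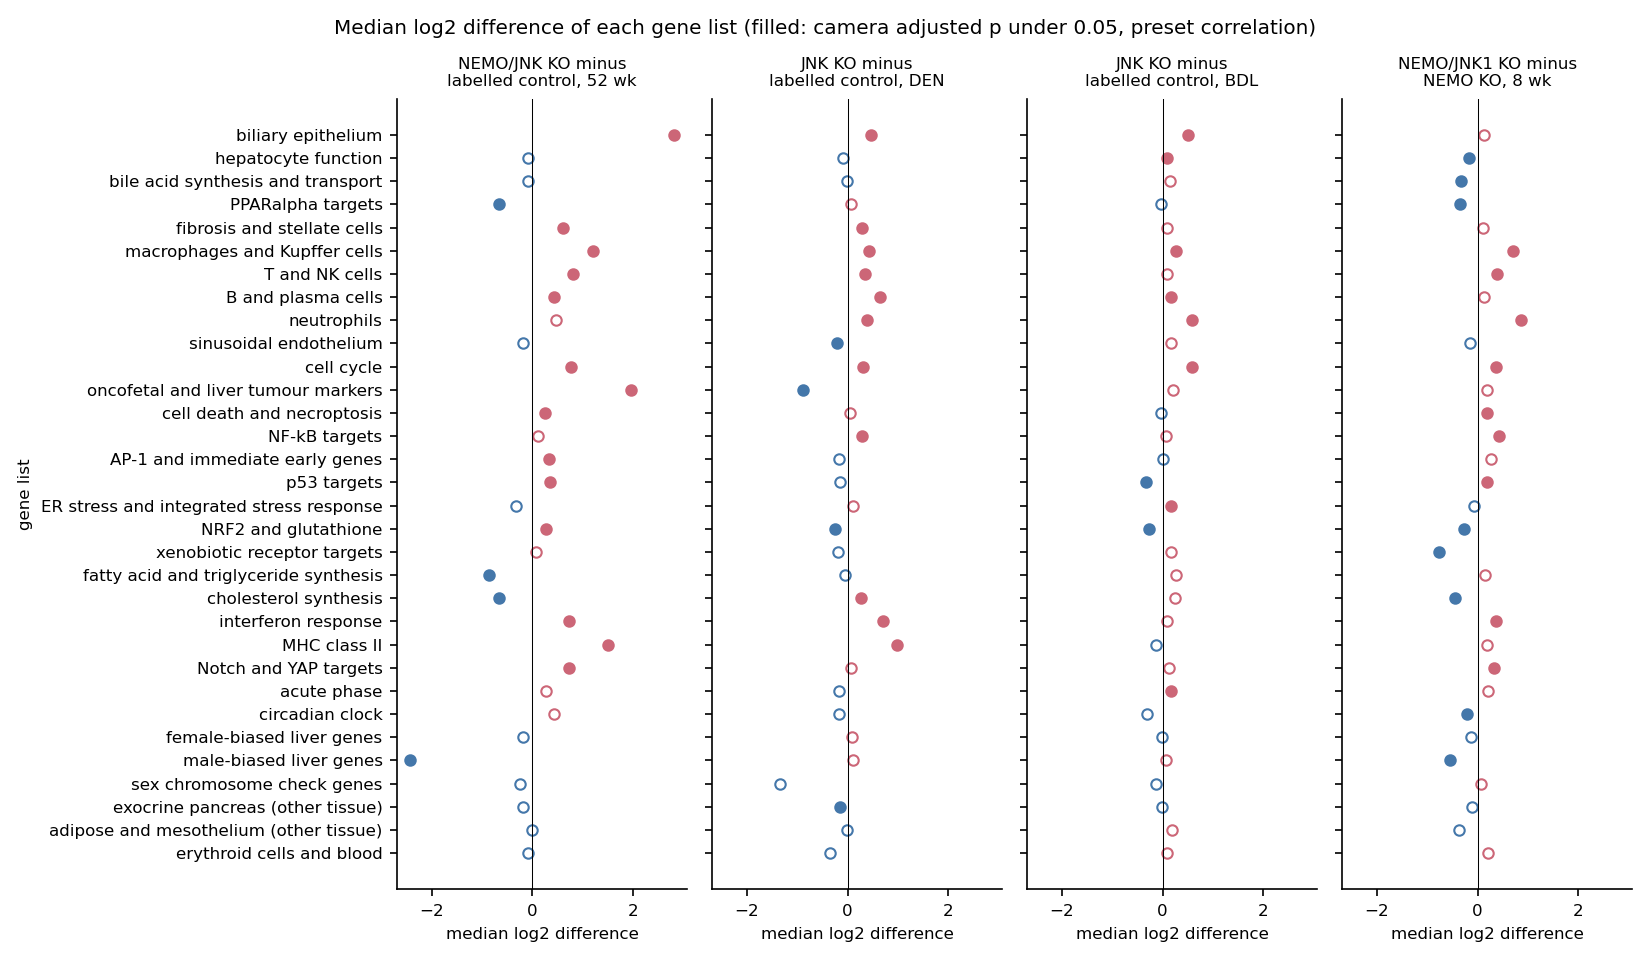
Median log2 difference of each of the 32 gene lists in the 4 genotype comparisons, with groups named by their labels, in red for positive and blue for other medians, with filled points where the camera adjusted p with its preset correlation was under 0.05. The biliary list stands at 2.81 and the male-biased list at −2.43 at 52 weeks, and the interferon list at 0.7 after diethylnitrosamine.

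The 8-week comparison concerns JNK1 in livers labelled as NEMO knockouts. The Ikbkg values did not show that loss of NEMO but cannot decide the label. Here 0 of 18820 genes passed by limma. The smallest p-values were those of Usp2, a clock-controlled ubiquitin protease, Ctse, an aspartic protease, and Mogat1, an enzyme of triglyceride synthesis, each with an adjusted p of 0.08. Ctse stood at 4.91 ± 0.64 in livers labelled NEMO/JNK1 and 8.96 ± 0.4 in livers labelled NEMO, Usp2 at 5.35 ± 0.03 and 6.77 ± 0.14, and Mogat1 at 5.64 ± 0.21 and 3.62 ± 0.26. Socs2, a growth hormone responsive inhibitor of cytokine signalling, stood at 9.11 ± 0.17 and 6.86 ± 0.47 (adjusted p = 0.233). Lepr, the leptin receptor, differed by 1.61 (SE 0.2), Nrp2 by 1.34 (SE 0.18) and Adamts4 by 0.97. Fndc10 differed by −1.2, Dpp4 by −0.99 and Nkiras1, an inhibitor of NF-kB signalling, by −0.8.

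Several lists stood apart at 8 weeks by camera with its preset correlation. Xenobiotic receptor targets had a median of −0.77 (camera adjusted p = 9.95e-07, adjusted p = 0.492 with an estimated correlation), and 4 of 15 were lower adjusted over the list alone. The cytochromes Cyp2c55 and Cyp2b10 differed by −3.25 (SE 0.49) and −2.83 (SE 0.76). NF-kB targets had a median of 0.42 (camera adjusted p = 9.95e-07, adjusted p = 0.492 with an estimated correlation), and 4 of 21 were higher adjusted over the list alone, among differences of 0.88 (SE 0.21) for the feedback inhibitor Tnfaip3 and 0.97 for the cytokine Il1b. All 17 cholesterol synthesis genes were lower on average (median −0.44, camera adjusted p = 0.000362, adjusted p = 0.571 with an estimated correlation), with Hmgcs1 at −0.95 and Msmo1 at −0.77. Macrophage genes (0.7, 4.97e-05), T and NK cell genes (0.39, 3.72e-05), neutrophil genes (0.87, 0.00622), the cell cycle (0.37, 4.97e-05), cell death (0.19, 0.0199), p53 targets (0.19, 0.0159), the interferon response (0.36, 0.00227) and Notch and YAP targets (0.33, 0.0356) were called upward. Of these, neutrophils and interferon had adjusted p = 0.578 with an estimated correlation, p53 targets 0.492 and the others 0.571. PPARalpha targets (−0.35, 0.000362), bile acid genes (−0.32, 0.00622), hepatocyte function (−0.17, 0.0113), NRF2 genes (−0.28, 0.0374), the circadian clock (−0.21, 0.00719) and male-biased genes (−0.54, 0.00364) were called downward. These had adjusted p = 0.571 with an estimated correlation, and NRF2 had 0.578.

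Several of those calls rested on single livers. Without NEMO/JNK1 replicate 2 the camera adjusted p was 0.879 for neutrophils, 0.198 for bile acid genes, 0.196 for cell death, 0.124 for hepatocyte function and NRF2, 0.0818 for interferon and 0.0749 for the clock. Without NEMO replicate 3 it was 0.966 for interferon, 0.67 for male-biased genes, 0.241 for hepatocyte function, 0.177 for cell death and 0.103 for Notch and YAP targets. The direction turned downward for neutrophils without NEMO/JNK1 replicate 2 and for interferon without NEMO replicate 3. Without NEMO replicate 1 the adjusted p was 0.061 for cholesterol synthesis, 0.0611 for p53 targets and 0.13 for NRF2, and without NEMO replicate 2 it was 0.0503 for Notch and YAP targets and 0.571 for NRF2. Without NEMO/JNK1 replicate 3 it was 0.485 for Notch and YAP targets and 0.0556 for p53 targets, and without NEMO/JNK1 replicate 1 it was 0.0542 for the clock and 0.056 for NRF2. With dim genes filtered out it was 0.117 for cell death and 0.05 for p53 and NRF2.

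The lists for biliary epithelium (median 0.12, camera adjusted p = 0.265), fibrosis (0.1, 0.334), B cells (0.12, 0.265), endothelium (−0.16, 0.275), oncofetal markers (0.18, 0.37), AP-1 (0.26, 0.189), ER stress (−0.08, 0.775) and fatty acid synthesis (0.14, 0.37) were not called at 8 weeks. At an unadjusted p under 0.05 there were 1442 genes, where 941 would be by chance, and the groups did not overlap for 14.37 percent of genes against 10 percent. Fry called 0 lists, array weights gave 2 genes and fitting all 24 arrays gave 57. All livers labelled NEMO came from another animal series than those labelled NEMO/JNK1 by their mouse identifiers, so that series and genotype cannot be told apart here.

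The comparison of the JNK effect between injuries asked where it differed, and 9 genes passed, 4 higher and 5 lower after bile duct ligation. Abhd1 had the smallest p. Its JNK effect was −3.12 after bile duct ligation and 0.03 after diethylnitrosamine. The difference of −3.15 (SE 0.26, limma adjusted p = 0.00133) was called under every setting tried. After ligation the mean of Abhd1 was 8.85 in livers labelled control and 5.74 in JNK knockouts. In the groups of the other experiments it lay between 5.89 and 6.35. The ligated livers labelled control thus stood apart, and their replicates 1 and 2 came from another animal series. Mybl1, a germ-cell transcription factor gene, had effects of −1.71 and −0.07 (difference −1.64, SE 0.16, adjusted p = 0.00504), and kept its call when any 1 liver was left out but not with all 24 arrays (0.396). The mean of Mybl1 was 6.34 in ligated livers labelled control and 4.63 in ligated JNK knockouts. After diethylnitrosamine it was 4.01 in livers labelled control and 3.95 in JNK knockouts. Ligated livers labelled control were thus the highest of these groups for Mybl1 as well. Efna3 had effects of 3.64 and 0 (difference 3.64, SE 0.45, adjusted p = 0.0177). It was not called without control replicate 1 after ligation (0.0639) or without JNK replicates 1 (0.0657), 2 (0.0709) or 3 (0.078). The list differences called by camera were upward for the acute phase (adjusted p = 0.00133), oncofetal markers (0.0034), endothelium (0.0076), hepatocyte function (0.0104) and fatty acid synthesis (0.0258). They were downward for the interferon response (median −0.52, 6.22e-09), MHC class II (0.0234) and fibrosis (0.0262). Each had adjusted p = 0.744 with an estimated correlation. The count of 9 was 26 without control replicate 1 after diethylnitrosamine, and 2 without JNK replicate 1 or 2 after ligation. It was 3 without control replicate 2 after diethylnitrosamine, control replicate 1 after ligation or JNK replicate 3 after ligation, 5 without JNK replicate 1 after diethylnitrosamine and 6 without control replicate 3 after diethylnitrosamine. With centring 5 genes were higher and 4 lower.

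The last comparison set livers labelled control after bile duct ligation against those after diethylnitrosamine, which also differed in the days since treatment. Of the ligated controls, replicates 1 and 2 came from another animal series than the other 4 livers, and this comparison was not fitted with the series as a block. Collagen genes were among those that rose. Col1a1 rose from 6.16 ± 0.15 after diethylnitrosamine to 9.24 ± 0.28 after ligation (SE 0.17, adjusted p = 0.000729), Col1a2 by 2.91 (SE 0.17) and Pdgfrb, a receptor of activated stellate cells, by 1.71 (SE 0.15). Fibrosis genes rose in 18 of 27 and fell in 0 (median 1.46, camera adjusted p = 6.27e-24, adjusted p = 0.423 with an estimated correlation), with 21 higher adjusted over the list alone. The 18 became 7 without the diethylnitrosamine control replicate 2, 10 without its replicate 3 and 8 without ligation control replicate 1. Biliary genes rose in 5 of 22 (median 1.12, camera adjusted p = 1.12e-07, adjusted p = 0.423 with an estimated correlation), among them Elf3 (2.9, SE 0.23), and 16 were higher adjusted over the list alone. Biliary counts were 10 without ligation control replicate 3 and 1 without any other liver. Neutrophil genes had a median of 1.22 (camera adjusted p = 1.68e-07, adjusted p = 0.423 with an estimated correlation), with 0 called over all genes and 12 higher adjusted over the list alone. Cyp2c39 rose from 7.36 ± 0.1 to 11.08 ± 0.22, and Wdr72 by 3.26 from 3.5, likewise within the range of Mapk9 without signal and so at most a lower bound. Cyp2c37 fell by 4.05 (SE 0.31), Rgs16, a clock-linked regulator of G proteins, by 3.8 (SE 0.25), Sdr9c7 by 3.38 and the glutamate transporter gene Slc1a2 by 2.8. PPARalpha targets fell in 3 of 25 (median −0.41, camera adjusted p = 2.85e-05, adjusted p = 0.473 with an estimated correlation), and in 0 without diethylnitrosamine control replicate 2 or ligation control replicate 1.

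By limma, 327 genes were higher and 139 lower after ligation in livers labelled control, or 230 and 192 with arrays centred, which moved the median of all genes to −0.14. The groups did not overlap for 24.95 percent of genes against 10 percent by chance. The count of 466 ranged widely with single livers. It was 234, 56 and 112 without diethylnitrosamine controls 1, 2 and 3, and 60, 219 and 858 without ligation controls 1, 2 and 3.

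Across genes, the log2 differences of the genotype comparisons correlated weakly, and genes are not independent replicates. Pearson's r was 0.27 between the 52-week and 8-week comparisons, 0.24 between the 52-week and diethylnitrosamine comparisons, 0.21 between the 2 injuries and 0.01 between 52 weeks and bile duct ligation. Spearman's rho for the same pairs was 0.31, 0.2, 0.12 and −0.05. Of the genes higher after bile duct ligation 55 were also higher at 52 weeks, where 20.42 would be by chance, and of those lower 9 were shared, where 8.291 would be.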

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

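The tests of the Mapk9 probe and of the Jnk2 allele, both tests of the male-biased genes, the check of neighbouring genes without the 2 gene clusters, and the splits of the 5 gene comparisons between 2 groups were chosen only after the result was seen.

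The JNK effect differed between bile duct ligation and diethylnitrosamine for 9 genes, by limma's test of the difference itself. On the log2 scale the difference was 3.64 for Efna3, 3.6 for A2m, 3.08 for Mmrn1 and 2.41 for Chrm3. It was −1.18 for Slc2a2, the glucose transporter of hepatocytes, −1.35 for Gpd1l, −1.64 for Mybl1, −2.14 for Catspere2 and −3.15 for Abhd1. Catspere2 had means of 2.92 and 2.95 after diethylnitrosamine and 2.91 in the JNK knockouts after ligation, near the level of Mapk9 without signal, so that its effect after diethylnitrosamine could not be measured and its value is not evidence of a different effect. Mmrn1 had means of 3.51 and 3.76 after diethylnitrosamine and 2.51 in livers labelled control after ligation, at or near the same level, so that the size of its difference is not reliable either. Chrm3, a muscarinic receptor, had differences of opposite sign, 1.26 after ligation and −1.14 after diethylnitrosamine, where 0 genes were called. Gpd1l had a difference of −0.73 and an adjusted p of 0.334 with the mean of its probe sets, and Slc2a2 an adjusted p of 0.135 with centring. Apart from Abhd1 and Mybl1, all the calls were lost without control replicate 1 after ligation (adjusted p from 0.0639 to 0.168), JNK replicate 1 (0.0657 to 0.158) or JNK replicate 2 (0.0709 to 0.115), and all but Mmrn1 without JNK replicate 3 (0.078 to 0.149). A2m, Mmrn1, Chrm3 and Slc2a2 were also lost without ligation control replicate 3 (0.0507 to 0.0918) or diethylnitrosamine control replicate 3 (0.0885 to 0.0965). Without diethylnitrosamine control replicate 2 only Efna3 was kept beside Abhd1 and Mybl1 (0.0532 to 0.125 for the others). A2m, Mmrn1, Catspere2 and Slc2a2 were lost without diethylnitrosamine JNK replicate 1 (0.0586 to 0.0783), A2m and Mmrn1 without its replicate 2 (0.0645), A2m without its replicate 3 (0.0817), and Mmrn1 (0.0677) and Slc2a2 (0.0748) without ligation control replicate 2. Of 100 splits of the livers within each treatment, 19 gave at least 9 genes, the real one included, so that chance could not be excluded for the count. The highest other split gave 294 genes. It set control replicates 2 and 3 and JNK replicate 2 of the diethylnitrosamine livers against the remaining 3, which is the number range of the mouse identifiers, and points to a structure of these samples. With that range as a block 27 genes passed.

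Signal also appeared in the 14338 probe sets with several gene names or none, which the comparisons by gene left out. Of these, 196 differed at 52 weeks (139 higher, 57 lower), 9 after bile duct ligation (7 higher, 2 lower) and 9 between the injuries in livers labelled control (4 higher, 5 lower). At 8 weeks 1 was higher, in the interaction 3 were lower, and after diethylnitrosamine 0 differed.

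The absence of Mapk9 signal from all 18 livers outside the 8-week experiment, livers labelled control included, was weighed first. A probe set that cannot detect the transcript is argued against by the mean of the 6 livers at 8 weeks, which lay 4.85 above the highest of the 18 others. A general difference between arrays is argued against as well, since Mapk9 was the 1 gene among all tested that separated the same livers by as much, and the next gap in group means was 2.37. The mice labelled control may carry the germline Jnk2-deficient allele that the growth protocol describes for the JNK line: the lowest liver at 8 weeks lay 4.48 above the highest liver labelled control in Mapk9, while Mapk8 in the 9 livers labelled control differed by only −0.08 from the livers labelled NEMO. The protocol itself names other mice as controls of the NEMO/JNK line, and wrong labels or another allele were not tested.

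For the genes that differed after bile duct ligation, genetic background remains a possible explanation. Pairs of called genes were counted if they lay within 10 genes of each other and their symbols differed in the first 3 letters. There were 50 such pairs, against a median of 36 in 2000 random sets (permutation p = 0.013). Without the pairs inside the chemokine and A2m clusters there were 41. The limit set before the test, from the upper tail of the random sets, was 46. Related genes with unlike symbols, such as the histone genes H4c3 and H1f1, still counted. Muc1 and Efna3 were also a pair. The 255 genes with the smallest limma p at 52 weeks gave 37 pairs (permutation p = 0.459). Animal series cannot be told apart from the genotype: over the 559 genes called without control replicate 3, chosen on the other livers and not the same set as the 255, that liver, from the series of the knockouts, had a median position of 0.53 between the knockouts (0) and the other controls (1), with quartiles of 0.14 and 0.9. Loss of JNK stays open too: 74.12 percent of the genes moved the same way after diethylnitrosamine, and the highest of the other splits of those 6 livers into labelled groups gave 63.53 percent. A difference in genetic background present in both experiments could give the same shared direction. This share therefore cannot separate loss of JNK from genetic background. All 3 livers labelled control lay outside the range of the 18 livers of the other experiments for 35 of the genes and all 3 knockouts for 30, so that both sides contribute.

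The lower male-biased genes at 52 weeks were weighed last. Female mice among the knockouts are argued against by Uty, whose lowest value in the 3 knockouts lay 3.44 above that of the liver with high Xist after diethylnitrosamine. A lower share of hepatocytes is argued against by 12 hepatocyte function genes with a mean under 12 in livers labelled control, whose median difference was −0.18 with quartiles of −0.52 and −0.01, against quartiles of −3.21 and −1.33 for the male-biased genes. The loss of NEMO and JNK in hepatocytes, named by the design, may lower this programme and stays a hypothesis. So do cholestasis, inflammation or hormone levels, which were not measured in the 52-week mice. In livers labelled control after ligation, Mup21 stood at 3.58, Mup3 at 7.86 and Slco1a1 at 4.32, about as low as in the 52-week knockouts. There, 12 of the 18 male-biased genes were lower and 6 higher than in livers labelled control after diethylnitrosamine. The median was −0.74 (camera adjusted p = 0.0441, adjusted p = 0.685 with an estimated correlation). With each array centred, which shifts all genes downward, the male-biased list median at 52 weeks was −2.76, against −0.41 for all hepatocyte function genes.

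With 3 livers against 3 there are 10 splits, too few for a share under 0.05. The real split gave 4048 genes at 52 weeks and the highest other 0, and 1 of the 10 splits gave as many. For bile duct ligation the values were 255, 0 and 1, and for the injuries in livers labelled control 466, 0 and 1. After diethylnitrosamine the real split gave 0 genes, so that all 10 gave as many, and the highest other gave 22. That split followed the number range of the mouse identifiers, and with the range as a block the comparison gave 0 genes. At 8 weeks the real split gave 0, the highest other 1, and all 10 gave as many. For gene lists the real and highest other values were 18 and 18 at 52 weeks, 15 and 21 after diethylnitrosamine, 10 and 14 after ligation and 17 and 17 at 8 weeks. As many lists came from 2, 7, 5 and 2 of the 10 splits.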

How the results depend on the processing

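The blocks by animal series and by identifier number range were chosen only after the result was seen. At 52 weeks 1348 values, each the difference of a named gene under 1 alternative, kept direction and side of the threshold. A further 58 lost and 12 gained a call and 0 changed sign. Counts of genes or lists and list medians were not among these values: 5 list medians turned negative with centring, which also left 1570 genes higher and 8942 lower. After bile duct ligation 904 kept both, 171 lost and 15 gained a call and 9 turned. The numbers were 1085, 0, 1 and 13 after diethylnitrosamine, 1014, 0, 9 and 11 at 8 weeks, 1510, 59, 15 and 1 for the interaction and 802, 194, 13 and 5 for the injuries in livers labelled control. The 52-week lists were called 18 times, but 0 with camera and an estimated correlation and 10 by fry. After diethylnitrosamine both gave 0, after ligation 0 and 2, and at 8 weeks both 0. Centring gave 10512 genes at 52 weeks. After ligation fitting all 24 arrays gave 116 genes, weights 391, and the animal series as a block, which sets 1 control liver against 3 knockouts, 118 genes and 16 lists. At 8 weeks fitting all 24 arrays gave 57 and weights 2. The interaction gave 68 with weights and 27 with the number range as a block. The injuries in livers labelled control gave 715 with all 24 arrays and 832 with weights. For these the cause was not tested.

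The replicate block changed the counts to 142 after ligation and 109 between the injuries. The block uses up degrees of freedom, but the cause of these falls was not tested. With the replicate block 3736 genes passed at 52 weeks, 0 after diethylnitrosamine, 0 at 8 weeks and 7 in the interaction. The deviations of livers with the same number correlated across genes with r of 0.36, 0.3 and 0.04 after diethylnitrosamine, 0.14, −0.07 and 0.04 after ligation, 0.02, 0.04 and 0.02 at 52 weeks, 0.01, −0.02 and −0.07 at 8 weeks and −0.15, −0.05 and −0.19 between the injuries.

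Leaving out 1 liver gave 2693 to 3671 genes and 15 to 19 lists at 52 weeks, 0 to 2 genes and 12 to 18 lists after diethylnitrosamine, 58 to 559 genes and 9 to 17 lists after ligation, 0 genes and 12 to 19 lists at 8 weeks, 2 to 26 genes in the interaction and 56 to 858 between the injuries. A smaller group has less power by construction, and the higher counts were not traced to a cause.

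Some differences turned sign under an alternative. With weights after diethylnitrosamine Ccn1 was −0.02 and Elovl3 −0.37. With the animal series as a block after ligation Alas2 was −0.21, Cyp2f2 −0.18, Insig1 −0.26, Sc5d −0.17 and Usp2 0.05. Mapk9 at 8 weeks was −0.04 with centring and −0.05 with weights, and between the injuries it was 0.04 with quantile normalisation. Uty between the injuries was −0.03 with quantile normalisation and −0.09 with centring. For these the cause was not tested. Leaving out 1 liver moved the following values over 0. After diethylnitrosamine Ikbkg ran from −0.35 to 0.01, Cbr3 from −1.85 to 0.14, Mapk9 from −0.21 to 0.04, Elovl3 from −0.20 to 2.53, Slc4a1 from −1.60 to 0.01, Npas2 from −0.13 to 1.06, Ccn1 from −0.15 to 1.14, Ccr2 from −0.03 to 1.64, Cyp3a16 from −0.33 to 2.02 and Hao2 from −0.04 to 1.97. After ligation H2-Eb1 ran from −0.47 to 0.02, Xist from −0.26 to 0.02, Rhag from −0.01 to 0.20 and Mapk9 from −0.01 to 0.14. At 8 weeks Uty ran from −0.09 to 0.32, Ctrb1 from −1.11 to 0.03, Des from −1.61 to 0.16, Mapk9 from −0.12 to 0.15, Slco1a1 from −1.92 to 0.42, Marco from −0.40 to 2.91, S100a8 from −0.15 to 2.21 and Slc4a1 from −0.20 to 0.91. Slc4a1 in the interaction ran from −0.01 to 1.61, and between the injuries Mapk9 ran from −0.18 to 0.07 and Cyp51 from −1.15 to 0.26. No detection call is given, so that a difference between values near the background, such as those of Mapk9 around 3.11, says little about the transcript.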

Other observations

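The levels of Ifi202b and BC018473 across groups were chosen only after the result was seen. At 52 weeks the gene lists not yet described went both ways. Circadian clock genes rose in 7 of 15 members and fell in 5 (median 0.42, camera adjusted p = 0.475). Camera tests a shared direction, while fry's mixed test, which counts changes in either direction, gave an unadjusted p of 0.00117. Arntl, an activator of the clock, was down by 1.36 (SE 0.14) and Nfil3 by 2.05, while Usp2 was up by 1.88. The list was set to look for technical or husbandry differences, and an effect of the hour of sampling was not tested. Xenobiotic receptor targets rose in 5 of 15 (median 0.06, camera adjusted p = 0.139), among them Cyp2a5 (1.23, not called with all 24 arrays at 0.0837) and Alas1 (1.22), and in 3 without control replicate 1, control replicate 3 or knockout replicate 2, while 3 fell with each array centred on its median. Acute phase genes rose in 4 of 25 and fell in 2 (median 0.26, camera adjusted p = 0.181). Socs3, a feedback inhibitor of cytokine signalling, rose by 1.6 and Il1rn by 1.28, and 10 members rose without control replicate 2, while 7 fell with arrays centred. ER stress genes rose in 3 of 19 and fell in 5, with a median of −0.32, a mean of 0.0 and a camera adjusted p of 0.336, and 0 fell without control replicate 3, knockout replicate 2 or knockout replicate 3. With arrays centred 11 ER stress genes fell, and with quantile normalisation 1. Nupr1 rose by 1.82 (SE 0.34) and Trib3 by 1.28. Sinusoidal endothelium rose in 2 of 16 and fell in 4 (median −0.18, camera adjusted p = 0.676), and 0 fell without control replicate 3, knockout replicate 1 or knockout replicate 2. With arrays centred 0 endothelial genes rose and 8 fell, and with quantile normalisation 1 rose and 1 fell.

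On the deposited scale, camera called none of the lists for other tissues or for sex at 52 weeks apart from the male-biased genes. Female-biased liver genes had 0 of 11 called (median −0.18, camera adjusted p = 0.42), with Cyp2b9 at −1.92 and Hao2 at −1.19, from 4.11 to 2.92, a level near background. Sex chromosome genes had 0 of 4 called (median −0.25, 0.144), and exocrine pancreas genes 1 of 11 lower (median −0.18, 0.407), which no omission of a single liver kept. Adipose and mesothelium genes had a median of 0.0, a mean of 0.33 and a camera adjusted p of 0.984, with the mesothelial gene Msln up by 3.45 (SE 0.29). Erythroid genes fell in 2 of 7 (median −0.09, 0.2), with Alas2, the heme synthesis gene of red cells, down by 1.84 (SE 0.18). With each array centred on its median, which lowers all genes, 5 of 11 female-biased, 4 of 4 sex chromosome, 8 of 11 pancreas, 4 of 9 adipose and mesothelium and 4 of 7 erythroid genes fell. With quantile normalisation 2 sex chromosome genes fell and 1 pancreas gene rose.

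Ifi202b and BC018473 varied widely between single livers of several groups. At 52 weeks the SD of BC018473 was 1.89 in livers labelled control and 2.82 in the knockouts. It was 2.07 in livers labelled control after diethylnitrosamine and 2.63 in livers labelled NEMO/JNK1. In the other groups it lay between 0.08 and 0.7. After bile duct ligation Ifi202b and BC018473 had means of 2.23 and 3.77 in JNK knockouts and 4.91 and 8.93 in livers labelled control.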
